A study of Mus musculus with 378 samples.

How the data were processed

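The study profiled single corneal and limbal epithelial cells of K14CreERT2-Confetti mice, in which tamoxifen switches on a fluorescent reporter in cells that express the Krt14-driven Cre. Per the labels, 3 mice per age, male and female, received tamoxifen on 3 consecutive days from 5, 17 or 59 weeks of age, and corneas with the limbal ring were collected 7 days after the first injection. Cells released with Dispase and trypsin were sorted into Confetti+ (coloured) and Confetti- (not coloured) epithelial cells at 6, 18 and 60 weeks, 63 cells per age and sort, and libraries were made by Smart-seq2. Each of the 378 samples is 1 cell.

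The authors quantified reads with Salmon 0.9.1 against a GRCm38 transcriptome, per the labels' protocols, and the labels also name tximport and Seurat 3.1.4 for their own later steps. The deposited files give, per the file headers, an estimated count of reads per transcript, which is not normalised. They also give, per the file headers, TPM per transcript, scaled by the authors' software to each cell's effective transcript lengths, and that effective length as another deposited column. The annotation release is not given in the sources used here. Transcript identifiers were matched to GENCODE M21 (GRCm38): 109474 of 109898 transcripts matched, 106978 of them with the same version, and the other 424 held a median of 0.138% of a cell's reads. Estimated counts were summed per gene, which gave 34530 genes, and rounded. Chromosome positions are those of GENCODE M21 on GRCm38. The TPM and the effective length were used for length-scaled counts, as an alternative.

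Gene-assigned reads per cell ranged from 303051 to 1471375, and cells had 614 to 7626 genes with a read. The labels state 288000 as the fewest reads, 778000 as the median, and 546 to 7246 genes with a median of 4758. Cells were kept with at least 2000 genes and a mitochondrial share of reads of at most 6.29%, the median plus 3 scaled median absolute deviations. This left out 24 of the 378 cells. Of those left out, 11 had too few genes and another 13 only too high a mitochondrial share. No doublet caller was run, because single cells were sorted into wells. Cells were clustered with scanpy 1.11.5 (2000 variable genes, 20 components, 15 neighbours, Leiden resolution 0.8) on Python 3.11.15, and a cluster was named only from markers fixed beforehand.

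No label ties a cell to a mouse, so cells were not treated as replicates. Counts were summed over the kept cells of each age and sort, which gave 6 sums. Confetti+ and Confetti- sums were compared with edgeR 4.0.16 (R 4.3.3), using TMM normalisation, the quasi-likelihood test with age as a block, Benjamini-Hochberg adjustment and 2 residual degrees of freedom. Genes were tested with at least 5 reads in at least 10% of the kept cells of at least 1 group. The p-values measure the spread between sums only. Of 26 gene lists fixed beforehand, 23 had at least 3 measured members and were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. The 3 others, markers of leukocytes, of vessels and blood, and of pigment and neural cells, had fewer. Members of a list were also adjusted over the list alone. DESeq2 1.42.0 was run as another tool.

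Each age and sort is 1 pool of cells, and the sorts of an age may come from the same mice and are not replicates of age, so ages were compared without a test. For 60 and 18 weeks against 6 weeks the log2 ratio of TMM-scaled counts (CPM, reads scaled to the same total in each sum, with 1 CPM added) was computed in each sort, over 7085 genes with at least 5 reads in at least 25% of the kept cells of a group. The share of cells with a gene counts cells with at least 5 reads after thinning every cell to 200000 reads, with exact (Clopper-Pearson) 95% intervals. Intervals cover counting error only. A list's median is set beside 10000 random lists of the same size matched on mean expression, as a description of these pools.

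The rule for named genes was fixed before the data were examined. For the sorts, since fewer than 10 genes passed, it takes the 10 genes with the highest and the 10 with the lowest fitted log2 ratio among those with the same sign at 3 ages and at least 5 reads in at least 25% of the cells of a group. For age, it takes the 12 highest and 12 lowest genes that moved the same way in both sorts, by the smaller of the ratios. The age ranking took genes with at least 5 reads, thinned, in at least 25% of the kept cells of either age compared, in each sort. Their share of cells had to move the same way as their ratio. Krt14, Krt5, Krt15, Krt12, Pax6, Trp63, Gpha2, Ifitm3, Cd63, Mki67, Cdkn1a and Cdkn2a are named in any case, and 2 to 4 members of each list; some members are not reported here. Predicted, ribosomal, mitochondrial and sex-linked genes were left out of the naming.

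The edgeR step was tested on 6 simulated sums of 9815 genes for the comparison of the sorts. It recovered 30.4% of genes changed 2-fold, 90.4% at 4-fold, 99.2% at 8-fold and 100% at 16-fold, and 6.10% of its calls were false. The changed genes were drawn from those with a mean of at least 20 CPM, and no age effect was simulated. Recovery was not tested below that level, where some of the ranked genes lie, such as Il1b (mean 8.59 CPM). With camera on those 9815 simulated genes, 5 and 6 of 200 unshifted lists in each of 2 runs had an unadjusted p under 0.05, and a list shifted by 1 log2 unit had p = 1.14e-39. That simulation does not cover lists whose members are correlated, so it does not test the preset correlation for them. Among the real lists the estimated correlation ran from -0.0439 for unfolded protein genes to 0.713 for stromal genes, with interferon genes at 0.246. The percentile of a list was tested on 7085 simulated genes for the age comparisons: 2, 49 and 98 of 100 lists lay outside the central 95% at a shift of 0, 0.5 and 1 log2 units. Lists with correlated members were not covered there either.

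Alternatives changed the tool, the normalisation, the gene filter, the cell filter, the age block, the weight of deep cells (thinning), the length scaling, the ages included, the pseudocount, the read threshold and the cluster resolution. Sums over cells with fewer than 5 reads of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, and over cells with fewer than 5 reads of each of Krt15, Krt4, Krt13 and Muc4, were added after the data had been seen. A planned split by Xist was not run, because Xist was not measured. A planned removal of clusters with leukocyte, stromal, endothelial or melanocyte markers removed nothing, since no cluster carried them. Raw reads were not used here.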

Results

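Single-cell expression was measured by Smart-seq2 in corneal and limbal epithelial cells of reporter mice at 6, 18 and 60 weeks of age, sorted as Confetti+ or Confetti-. Each age and sort held 63 cells, 378 in all. Cells had a median of 5032.5 genes. The kept Confetti+ cells numbered 61, 63 and 63 at 6, 18 and 60 weeks, with median reads of 735924, 812674 and 885736. The kept Confetti- cells numbered 62, 58 and 47, with median reads of 800681, 918396.5 and 791652. Of the Confetti- cells at 60 weeks, 16 were left out, 25.4% (95% interval 15.3 to 37.9%), against at most 5 in any other group.

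The sorts also differed in cells with Y-linked reads, which come from male mice. Among Confetti+ cells, 50.8% (37.7 to 63.9%), 76.2% (63.8 to 86.02%) and 60.3% (47.2 to 72.4%) had at least 5 such reads at 6, 18 and 60 weeks. Among Confetti- cells the shares were 9.68% (3.63 to 19.9%), 46.6% (33.3 to 60.1%) and 10.6% (3.55 to 23.1%). The Confetti- cells counted had a median of 5.5 Y-linked reads at 6 weeks and 15 at 60 weeks, far fewer than in the Confetti+ cells, so they lie near the limit of 5 reads and the male cells among them are uncertain. The mix of mice thus differed between the sorts of an age, and the mouse of each cell is not given in the sources used here.

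**Figure D1:**
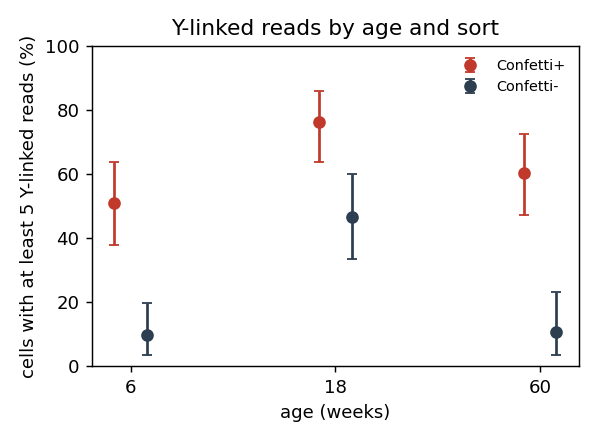
Percentage of kept cells with at least 5 reads of Y-linked genes (vertical axis) by age in weeks (horizontal axis), for Confetti+ and Confetti- cells, with exact 95% binomial intervals. Confetti+ cells lie above Confetti- cells at each age, 50.8% against 9.68% at 6 weeks.

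The comparison of Confetti+ with Confetti- cells asks how cells in which the Krt14-driven reporter was switched on differ from those in which it was not. By gene list at a preset correlation, Confetti- cells had more transcripts of interferon-stimulated genes, of innate immune genes and of limbal progenitor markers, and Confetti+ cells more of cholesterol synthesis and basal adhesion genes. With an estimated correlation 0 of the 23 lists passed (lowest camera adjusted p = 0.262). Ifitm1, an interferon-induced membrane protein gene, stood at a mean of 105.2 CPM in the 3 Confetti+ sums and 589 CPM in the 3 Confetti- sums. Krt14 itself differed little, at 5173 CPM in Confetti+ and 5857 CPM in Confetti- sums (log2 ratio -0.18, SE 0.21, edgeR adjusted p = 0.905), and the sign of its ratio turned with the setting.

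Of 9815 genes tested, edgeR called 0 higher in Confetti+ and 2 higher in Confetti- sums, which are named here after their values were seen. At an unadjusted edgeR p under 0.05 there were 721 genes, where chance gives 490.75 over both directions. Of the 721, 448 were higher in Confetti-. DESeq2 called 53 higher in Confetti+ and 1.71% of the tested genes higher in Confetti-. Ifitm1 (chromosome 7, 140967221 to 140969825) had a log2 ratio of Confetti+ over Confetti- of -2.47 (SE 0.17, edgeR adjusted p = 0.0323) and was lower in Confetti+ at 3 of 3 ages, at -2.61, -2.61 and -2.16. Serpinb2, a serine protease inhibitor gene (chromosome 1, 107511423 to 107535478), stood at a mean of 1.45 CPM in Confetti+ and 261.02 CPM in Confetti- sums (log2 ratio -7.75, SE 0.57, edgeR adjusted p = 0.0323) and was lower in Confetti+ at 3 of 3 ages. Its Confetti- levels were 27.6, 41.9 and 713.5 CPM at 6, 18 and 60 weeks, so 60 weeks carried most of that mean. It was detected in 11.3%, 8.62% and 17.0% of Confetti- cells at these ages. Without 6 weeks the adjusted p was 0.102 for Ifitm1 and 0.0950 for Serpinb2, and without 18 weeks it was 0.0919 for Ifitm1. In cells with fewer than 5 Y-linked reads, edgeR called 0 genes, with 439 at an unadjusted p under 0.05; DESeq2 was not run on those cells. The ratio of Ifitm1 there was -2.70 (SE 0.56, against 0.17 in all kept cells; adjusted p = 0.928) and that of Serpinb2 -10.51 (SE 1.58, against 0.57; adjusted p = 0.726), with wider errors and no smaller ratios in those cells. Thinned, Serpinb2 was called there (adjusted p = 0.0442). In cells without Krt15, Krt4, Krt13 or Muc4 the ratios were smaller, at -1.42 (SE 0.65) for Ifitm1 and -5.10 (SE 3.82) for Serpinb2, and neither was called (adjusted p = 0.997). Without the age block the adjusted p were 0.206 and 0.315, and with length-scaled counts that of Serpinb2 was 0.0884.

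Ranked by size, the 10 genes highest in Confetti+ were Il1b, the cytokine interleukin 1 beta (13.4 against 3.78 CPM), Olfr648 (log2 ratio 2.39), Dlx5 (2.06), Sdccag8 (1.90), Chst15 (1.86), the efflux transporter gene Abcg2 (1.74), Cyp2b19 (1.74), Zfp276 (1.67), Olfr147 (1.66) and Ralgapa1 (1.63). Il1b had 0 CPM in Confetti- cells at 6 weeks, and its fitted ratio went from 1.03 to 4.89 over the settings. None of the 10 passed edgeR, with adjusted p from 0.220 for Abcg2 to 0.777 for Il1b, while DESeq2 called some, among them Abcg2 (adjusted p = 2.41e-06). The 10 highest in Confetti- were Lurap1l (0.737 against 10.6 CPM), the interleukin 1 receptor antagonist gene Il1rn (-5.69), the interferon-induced gene Ifit3 (-4.60), the limbal keratin gene Krt15 (-4.50), Klk10 (-4.34), Ifi209 (-4.29), Slfn2 (-4.14), the metalloprotease gene Adam8 (-3.81), the oestrogen receptor gene Esr1 (-3.51) and Liph (-3.42). The lowest edgeR adjusted p among them were 0.0643 for Ifit3 and Adam8 and 0.0967 for Slfn2. The ratio of Klk10 turned to 0.69 in cells without Krt15, Krt4, Krt13 or Muc4. That of Chst15 turned to -0.53 in cells with fewer than 5 Y-linked reads. Ifit3 and the Ifitm genes have close paralogs, and how reads divide among such copies is uncertain.

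Other genes fixed beforehand did not pass edgeR either. DESeq2 called Gpha2 (adjusted p = 2.53e-13), Ifitm3 (5.64e-05), Cd63 (5.57e-04) and Mki67 (0.0306). With no gene filter, the 25% filter, thinned counts or without 60 weeks, edgeR called Gpha2. The limbal gene Gpha2 stood at 25.6 CPM in Confetti+ and 94.7 CPM in Confetti- sums (log2 ratio -2.03, SE 0.22, edgeR adjusted p = 0.0647). Ifitm3 (-1.21) and Cd63 (-1.66) had adjusted p of 0.254 and 0.347. The basal keratin gene Krt5 (0.08), the corneal keratin gene Krt12 (0.37), the eye master regulator Pax6 (-0.38), the basal cell transcription factor gene Trp63 (0.67), the proliferation marker Mki67 (2.69) and the cell cycle inhibitor gene Cdkn1a (-0.21) had edgeR adjusted p from 0.655 to 0.930. The senescence marker Cdkn2a had 2 reads over all kept cells and was not tested. No cell had 5 of its reads, 0 of the kept cells, which allows a share of up to 0.847% (3 counts of the total). That limits cells with 5 reads, not cells that express the gene.

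By gene list, camera called 14 of 23 lists, and 0 with an estimated correlation. Interferon-stimulated genes were higher in Confetti- sums, with a median log2 ratio of -1.03 over 26 members (camera adjusted p = 4.91e-14; adjusted p = 0.262 with an estimated correlation). Of these, 12 were lower in Confetti+ at 3 of 3 ages and 0 higher. Adjusted over the list alone 4 passed, Ifit3, Irf1, Gbp2 and Ifitm3, and over all genes 0. Ifit3 (-4.60) had the largest fitted ratio. Rtp4 and Usp18 followed by fitted ratio (-3.75 and -2.24) but were higher in Confetti+ at 60 weeks, and their mean levels differed little (4.53 against 5.00 and 8.19 against 10.3 CPM). Limbal progenitor markers were also higher in Confetti- sums (median -1.17 over 16 members, camera adjusted p = 2.86e-07; adjusted p = 0.292 with an estimated correlation). Adjusted over the list alone 10 passed, of which 9 were higher in Confetti-, led by Krt15 (-4.50), Krt17 (-3.08), the stress-induced transcription factor gene Atf3 (-2.30) and Gpha2 (-2.03), and Abcg2 was higher in Confetti+. In cells with at least 3000 genes the median was -0.62. Innate immune and NF-kB genes were higher in Confetti- sums (median -0.62 over 23 members, camera adjusted p = 1.10e-08; adjusted p = 0.262 with an estimated correlation), with 10 lower in Confetti+ at 3 of 3 ages and 2 higher. Adjusted over the list alone 7 passed, among them Il1rn (2.66 against 95.4 CPM) and the receptor gene Tlr2 (2.80 against 18.7 CPM). With the filter at 25% of cells the median was -0.35.

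Cholesterol synthesis and uptake genes were higher in Confetti+ sums, with a median log2 ratio of 0.56 over 20 members (camera adjusted p = 1.66e-12; adjusted p = 0.262 with an estimated correlation). Of these, 13 were higher in Confetti+ at 3 of 3 ages and 0 lower, and adjusted over the list alone 9 passed. The estimated correlation of this list was -0.000774, under the preset 0.01. Its unadjusted camera p was 1.44e-13 at the preset and 0.0150 at the estimated correlation. A higher correlation thus does not account for the change in this list. Insig1 (1.28), which restrains sterol synthesis, and Sqle (0.90), which encodes squalene epoxidase, had ratios among the largest. Basal keratin and adhesion genes were higher in Confetti+ sums (median 0.46 over 18 members, camera adjusted p = 4.64e-08; adjusted p = 0.278 with an estimated correlation). Over all 378 cells the median was 0.26 (camera adjusted p = 8.44e-04), and in cells without Krt15, Krt4, Krt13 or Muc4 it was 0.24. Of the 18 members, 12 were higher at 3 of 3 ages and 0 lower, and adjusted over the list alone 4 passed, among them the laminin gene Lama3 (1.08), the hemidesmosome collagen gene Col17a1 (0.80) and the integrin gene Itgb4 (0.77).

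Further lists were higher in Confetti- sums. Superficial barrier and junction genes had a median of -0.31 (camera adjusted p = 4.18e-06; adjusted p = 0.262 with an estimated correlation), and adjusted over the list alone 2 of 24 passed, the claudin genes Cldn4 (-2.17) and Cldn1 (-1.60). In cells with fewer than 5 Y-linked reads their camera adjusted p was 0.276, and without 60 weeks their median was -0.093. Immediate early genes, which tissue dissociation also raises, had a median of -0.41 (camera adjusted p = 4.12e-06; adjusted p = 0.363 with an estimated correlation), led by Nr4a1 (-2.47), 1 of 2 members past the test adjusted over the list alone. In cells without Krt15, Krt4, Krt13 or Muc4 their median was 0.0195 (camera adjusted p = 0.115), and without 60 weeks it was -0.26. Squamous genes had a median of -1.15 (camera adjusted p = 1.03e-05; adjusted p = 0.262 with an estimated correlation), with Cnfn at -2.17 and Sprr1a at -1.39, and adjusted over the list alone 0 passed. Without 60 weeks their median was -0.54. Class I antigen presentation genes had a median of -0.36 (camera adjusted p = 0.00122; adjusted p = 0.278 with an estimated correlation), with B2m at -0.76, and a median of -0.18 (adjusted p = 0.0922) without 18 weeks and of -0.13 in cells without Krt15, Krt4, Krt13 or Muc4.

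Lists of markers of other cells were higher in Confetti- sums in the fit, but not at 6 weeks, where the medians of the conjunctival and stromal lists were 0.07 and 0.05. Not all members mark other cells here. Aqp5, of the conjunctival list, was detected in 89.4 to 98.4% of the cells of each group. Of the stromal list, Aldh1a3 was detected in 50.8 to 82.3% and Slc4a11 in 46.8 to 74.6%. The medians thus do not measure the share of other cells. Conjunctival and goblet genes had a median of -2.28 over 8 members (camera adjusted p = 1.23e-04; adjusted p = 0.262 with an estimated correlation). The conjunctival keratin gene Krt4 stood at a mean of 0.276 CPM in Confetti+ and 177.6 CPM in Confetti- sums, and Krt7 at 0.371 and 24.8 CPM. The list's median was 0.19 with the filter at 25% of cells, its camera adjusted p was 0.119 in cells with fewer than 5 Y-linked reads, and its median was -0.02 in cells without Krt15, Krt4, Krt13 or Muc4 (adjusted p = 0.618). Stromal genes had a median of -1.002 over 4 members (camera adjusted p = 0.00122; adjusted p = 0.363 with an estimated correlation), and the keratocyte proteoglycan gene Dcn, detected in 10.6% of Confetti- cells at 60 weeks, stood at a mean of 0.0580 CPM in Confetti+ and 110.9 CPM in Confetti- sums. At 18 weeks Dcn was detected in 1 of 58 Confetti- cells. Other members were low or absent in Confetti- cells at 60 weeks. Kera, Lum, Col3a1 and Col6a1 had 0 CPM there and Col1a1 0.0259 CPM, while Col1a2, Vim, Col8a1 and Col8a2 had 5.54 to 13.1 CPM. Without 18 weeks the camera adjusted p of the stromal list was 0.0563, and without 60 weeks its median was -0.66.

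Lists higher in Confetti+ sums included glycolysis genes (median 0.18, camera adjusted p = 0.00700; adjusted p = 0.430 with an estimated correlation), led by Ankrd37 (2.14), Slc16a3 (1.32) and the glucose transporter gene Slc2a1 (1.11), the last of which was the only member past the test adjusted over the list alone. Their median was 0.00793 in cells without Krt15, Krt4, Krt13 or Muc4 (camera adjusted p = 0.708), 0.14 without 18 weeks (0.286) and 0.11 in thinned cells with fewer than 5 Y-linked reads (0.0544). Cell cycle genes had a median of 0.61 (camera adjusted p = 0.0101; adjusted p = 0.716 with an estimated correlation), with Mki67 (2.69) and Ccna2 (2.38), but their median was -0.82 at 60 weeks and -0.08 in the fit without 6 weeks, and adjusted over the list alone 0 passed. Sex-linked genes had a median of 4.31 over 4 Y-linked members (camera adjusted p = 2.78e-05; adjusted p = 0.262 with an estimated correlation), but 2.77, 7.73 and 2.59 without 6, 18 and 60 weeks and 1.44 without the age block. The other 9 lists did not pass camera. Their adjusted p were 0.108 for senescence genes, 0.244 for mitochondrially encoded genes, 0.270 for nuclear respiratory chain genes, 0.466 for unfolded protein genes, 0.573 for Wnt, Notch and BMP genes, 0.877 for corneal differentiation genes, 0.904 for ribosomal protein genes, and 0.910 for antioxidant and for circadian genes. Of these, senescence genes had a median of 0.07 but were lower in Confetti+ past camera with no gene filter (-0.36, adjusted p = 1.06e-04), without 6 weeks (-0.37, adjusted p = 1.99e-04) and in thinned cells with fewer than 5 Y-linked reads (-0.25, adjusted p = 0.0349). Mitochondrially encoded genes passed without 18 weeks (0.30, adjusted p = 0.00491).

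**Figure D2:**
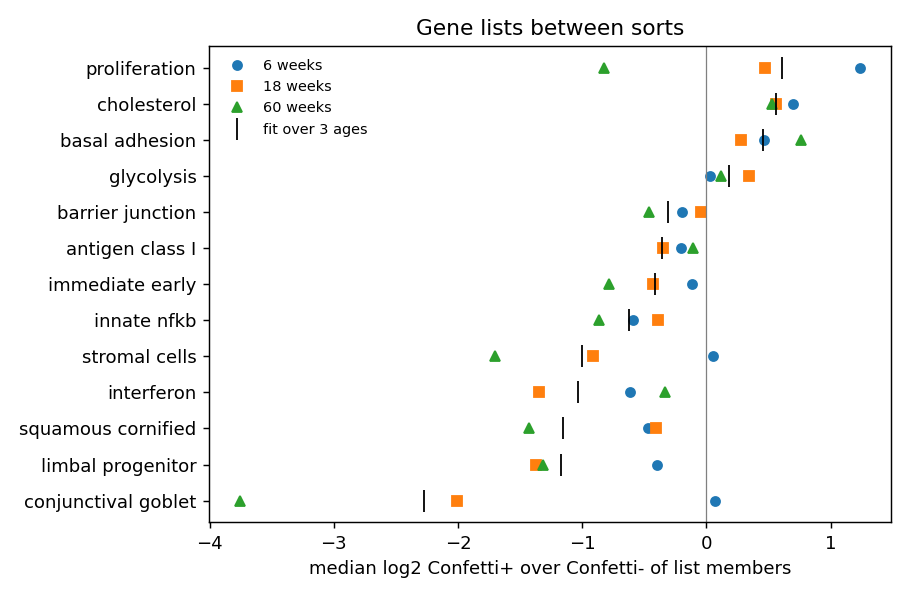
Median log2 ratio of Confetti+ over Confetti- (horizontal axis) of the members of 13 gene lists that passed camera, sex-linked genes left out, at 6, 18 and 60 weeks (points) and in the fit over 3 ages (bars). Interferon genes lie at -1.03 and cholesterol genes at 0.56 in the fit.

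The comparison of 60 with 6 weeks asks how the epithelium differs in aged mice. It describes 1 pool of cells per age and sort. The sorts of an age may come from the same mice and are not replicates of age, so no test of age was run. The limbal markers Krt15 and Gpha2 were more frequent in aged Confetti- cells. Krt15 was detected in 16.1% (8.02 to 27.7%) of Confetti- cells at 6 weeks, 37.9% (25.5 to 51.6%) at 18 weeks and 68.1% (52.9 to 80.9%) at 60 weeks, and unthinned in 17.7%, 39.7% and 68.1%. Its level there was 143.9, 1028 and 2548 CPM. In Confetti+ cells its share was 8.20%, 7.94% and 9.52%. Gpha2 was detected in 22.6%, 31.0% and 57.4% (42.2 to 71.7%) of Confetti- cells and in 9.84%, 22.2% and 39.7% (27.6 to 52.8%) of Confetti+ cells, with levels of 38.1, 83.7 and 162.2 CPM and of 8.67, 17.3 and 50.7 CPM. Unthinned, its share at 6 and 60 weeks was 29.0% and 61.7% in Confetti- cells and 21.3% and 46.0% in Confetti+ cells. Trp63, also on the limbal progenitor list, was detected in 77.4% of Confetti- cells at 6 weeks and 42.6% (28.3 to 57.8%) at 60 weeks. Its levels there were 139.5 and 132.4 CPM, and unthinned its shares were 85.5% and 57.4%. Abcg2, another member, was detected in 32.3%, 15.5% and 19.1% of Confetti- cells at 6, 18 and 60 weeks. By level, 12 of the 15 measured members were higher in Confetti- cells at 60 than at 6 weeks. Krt13, a conjunctival keratin gene, was detected in 6.45% of Confetti- cells at 6 weeks and 29.8% (17.3 to 44.9%) at 60 weeks.

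**Figure D3:**
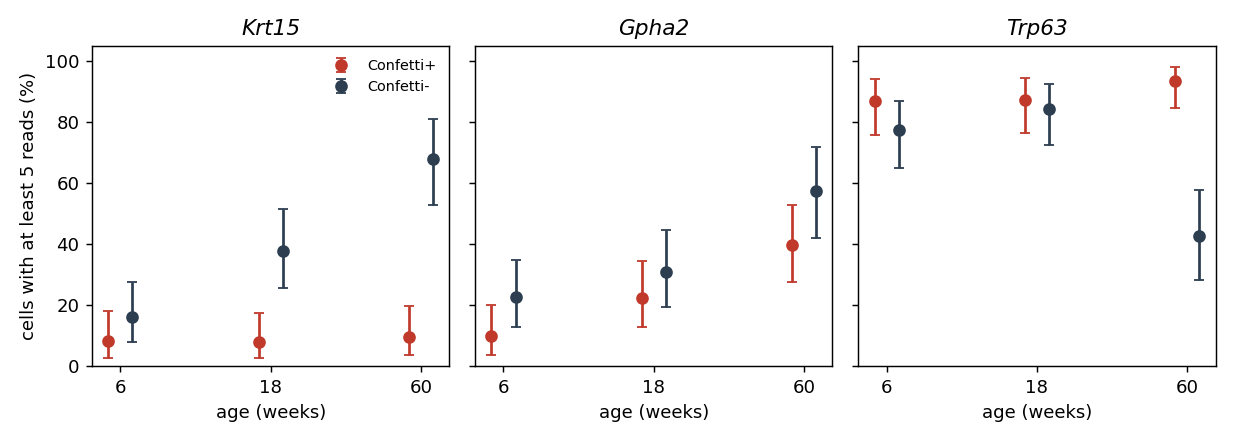
Percentage of kept cells with at least 5 reads at a thinned depth (vertical axis) of Krt15, Gpha2 and Trp63 by age in weeks (horizontal axis), for Confetti+ and Confetti- cells, with exact 95% binomial intervals. The Krt15 share in Confetti- cells is 16.1% at 6 weeks and 68.1% at 60 weeks.

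Interferon-stimulated genes were higher at 60 weeks in both sorts, with a median log2 ratio over 6 weeks of 1.13 in Confetti+ and 0.66 in Confetti- cells. With 10 CPM added the medians were 0.58 and 0.56, and over all 378 cells 0.58 and 0.62. Of 17 measured members 14 were higher in both sorts and 0 lower in both, and the medians lay at percentiles 100 and 99.97 of random lists. Most members were also detected in more Confetti- cells at 60 weeks, but Irf7, Irf9, Irf1, Oas1a and Ifi35 in fewer. The share of Irf9 was 45.2% at 6 and 29.8% at 60 weeks. That of Irgm1 was 35.5% and 36.2%, and Oasl1 was in 3.28% and 7.94% of Confetti+ cells. Oasl1 (1.90 in Confetti+ and 3.18 in Confetti-) and the interferon-induced GTPase gene Irgm1 (1.56 and 2.11) had the largest ratios by the smaller of the sorts' values, while Xaf1 (2.48 and 0.37) was highest in Confetti+. The limbal progenitor list had medians of 0.18 in Confetti+ and 0.94 in Confetti- cells, at percentiles 95.2 and 100 of random lists. It holds the stress genes Atf3 and Socs3, and immediate early genes had medians of -0.03 and 0.52, at percentiles 56.8 and 100. Wnt, Notch and BMP genes had medians of 0.36 and 0.35, at percentiles 99.5 and 99.1, but 0.76 and 0.14 in cells with fewer than 5 Y-linked reads and 0.39 and 0.75 over all 378 cells. Glycolysis genes had medians of -0.24 and -0.27, at percentiles 1.11 and 2.38, but the mean of the medians was 0.04 in cells with fewer than 5 Y-linked reads.

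Among single genes, the 12 highest at 60 weeks in both sorts were led by Areg, which encodes the growth factor amphiregulin (log2 ratio 2.07 in Confetti+ and 3.03 in Confetti-), and by Gpha2 (2.42 and 2.06), whose mean of the sorts was 1.37 in cells with fewer than 5 Y-linked reads. The apolipoprotein gene Apoe (1.61 and 2.07) and Irgm1 (1.56 and 2.11) followed among the genes eligible for naming. The others were Gmds, Apmap, Acsm1, Nup98, Rcan1, Cldn1, Gsta3 and Pon3. The ranking had an expression floor of 20 CPM, and 4414 genes were eligible at 60 weeks. Oasl1 (1.90 and 3.18) was not among the 12, though the smaller of its ratios exceeded that of Apoe. It was detected in 3.28% and 7.94% of Confetti+ cells at the ages compared. These values lie under the share of cells that the ranking required in each sort. The 12 lowest were led by the mitophagy gene Bnip3 (-2.17 and -1.87), Fam89a (-1.79 and -1.93) and Clba1 (-2.29 and -1.75), with Spata6, Myadm, Tnip1, Natd1, Nfe2l3, Akr1b8, Ifngr2, Ube2d1 and Rhoc. Krt14 went opposite ways in the sorts (-0.39 and 0.36), Krt12 differed mainly in Confetti- cells (0.06 and -0.62), and Cdkn1a had ratios of 0.09 and 0.67. Over all 7085 genes, which are not independent, the ratios of the sorts had r = 0.113 and rho = 0.107, and 53.4% had the same sign.

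The comparison of 18 with 6 weeks covers the young adult. Immediate early genes were higher at 18 weeks in both sorts, with medians of 0.57 in Confetti+ and 0.67 in Confetti- cells, both at percentile 100 of random lists, and 22 of 24 members higher in both. The transcription factor genes Egr1 (1.24 and 4.54) and Atf3 (1.21 and 2.12) had large ratios. Glycolysis genes were lower, with medians of -0.27 and -0.53 at percentiles 1.63 and 0.02, and 14 of 20 lower in both sorts, but the Confetti+ median was -0.10 in cells with fewer than 5 Y-linked reads. Unfolded protein genes had medians of 0.18 and 0.24, at percentiles 99.3 and 99.8. Interferon genes had medians of -0.47 and -0.08 at 18 weeks, at percentiles 0.040 and 38.9, but in cells with fewer than 5 Y-linked reads the medians were 0.27 and -0.32. With thinned counts the Confetti+ median was -0.23, and with the filter at 10% of cells the Confetti- median was 0.24. The limbal progenitor list had medians of -0.19 in Confetti+ (-0.38 thinned) and 0.84 in Confetti- cells.

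The 12 highest genes at 18 weeks, ranked by the same rule, were led by Areg (2.12 and 3.16), Spon2 (1.505 and 1.949) and Acsm1 (1.44 and 1.47). The others were Egr1, Atf3, Kazn, Tfdp2, Apmap, Cd3eap, Surf6, Tgif2 and Tshz2. The 12 lowest were led by Fabp5, which encodes a fatty acid binding protein (-1.93 and -1.97), Bnip3 (-1.71 and -2.98) and Prss22 (-1.32 and -1.23), with Ube2d1, P4ha1, Eno1b, Aldh1a3, Mrpl53, Cir1, Spata6, Krt6b and Zfpl1. Across the 7085 genes the sorts had r = 0.136 and rho = 0.135, and 56.1% had the same sign. Acsm1, Areg and Apmap were among the highest and Bnip3, Spata6 and Ube2d1 among the lowest at both ages, and both ratios share the pools at 6 weeks.

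**Figure D4:**
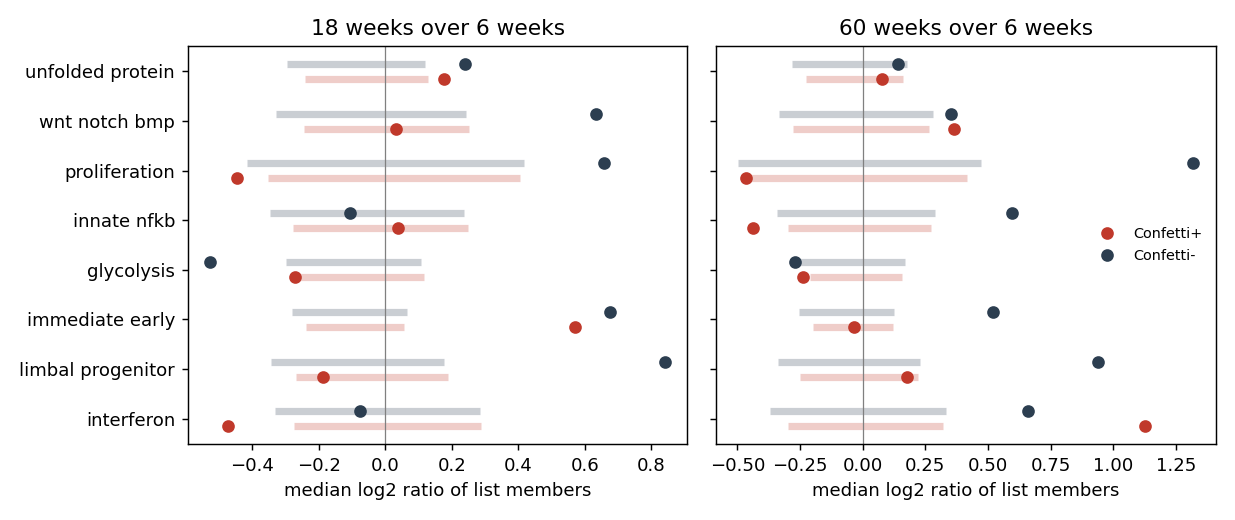
Median log2 ratio over 6 weeks (horizontal axis) of 8 gene lists at 18 and at 60 weeks in Confetti+ and Confetti- cells (points), with the central 95% of random lists (pale bars). At 60 weeks interferon genes lie at 1.13 in Confetti+ and 0.66 in Confetti- cells.

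Clustering of the kept cells gave 7 clusters. The cycling-like cluster of 21 cells carried 8 of 8 markers and was led by Nuf2, Smc2 and Pbk. A cluster of 56 cells was led by stress and signalling genes, among them Igfbp2, Gem, Socs3, Nr4a1 and Gadd45b. It had 8 of 8 limbal progenitor markers in at least 25% of its cells but 1 among its 10 leading genes, and stayed unnamed. So did a cluster of 60 cells led by Serpinb2, Muc4, Slc5a8, Akr1b7 and Krt13, and the other 4. The 10 leading genes of the cluster led by Serpinb2 also held Ifit3b and Ifi209. Serpinb2 and Ifi209 were detected in 28.3% and 36.7% of its cells, each against 1.70% of the other kept cells. Sizes of clusters were not compared between groups, because their defining genes differ between them.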

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

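Chosen only after the result was seen were the tests in cells with few Y-linked reads for the 5 lists, the gap in Y-linked shares, the detection of Krt15 in gene-rich cells, the share of Krt13, the interferon genes without their highest cells and by sort in cells with few Y-linked reads, and the leukocyte genes. The tests in cells without limbal and superficial markers and of interferon genes over both sorts in cells with few Y-linked reads were written before their result was seen, and so was the count over splits.

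The sorts differed in interferon, innate immune, limbal progenitor, cholesterol and basal adhesion genes at a preset correlation. With an estimated correlation none of these lists passed (adjusted p = 0.262 to 0.292). The share of male cells is an unlikely source, since 5 of the 5 lists kept their direction and most of their size in cells with fewer than 5 Y-linked reads. Limbal and superficial cells in the Confetti- sort cannot be told apart as a source. Without cells that have Krt15, Krt4, Krt13 or Muc4, 3 of the other 4 lists stayed above the limit set by more than the SD over fits without 1 age. They kept 68.7% of the median for interferon, 67.01% for innate immune and 64.6% for cholesterol genes. Basal adhesion kept 53.0% and limbal progenitor genes 39.0%, with 13 Confetti- cells left at 60 weeks. But the filter may leave such cells in. The limbal progenitor list still differed in the cells left (median -0.46, camera adjusted p = 0.0122). Muc4 was detected, thinned, in 75% of the cells of the cluster led by Serpinb2 and Muc4. Different mice in the 2 sorts cannot be told apart from the sort, as Confetti+ exceeded Confetti- by 41.1 percentage points in Y-linked share at 6 weeks and no label gives the mouse. Of the 10 splits of the 6 sums, too few for a share under 0.05, the real one called 2 genes and the highest other 1, so 1 of the 10, the real one, gave as many. Some of the others part the sorts of only 1 age and are unlike the real one, which parts 3. The most genes at an unadjusted p under 0.05 in such a split were 1173, against 721 in the real one.

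The limbal markers Krt15 and Gpha2, but not Trp63 or Abcg2, were more frequent with age in Confetti- cells. Poor cells argue little for it, since among cells with at least 3000 genes Krt15 was detected in 63.2% (46.0 to 78.2%) at 60 weeks, above the 6-week interval. The mix of sexes is an unlikely source of the difference between 6 and 60 weeks. The Y-linked shares of Confetti- cells then differed by 0.961 percentage points, though the counted cells had a median of only 5.5 and 15 such reads. At 18 weeks that share was 46.6%, against 9.68% at 6 weeks, so for 18 weeks the mix of sexes cannot be told apart. How much limbus and conjunctiva each pool held cannot be told apart from a change of the cells, since Krt13 too was detected in 29.8% of Confetti- cells at 60 weeks, and age itself stays open and untested.

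Interferon genes were higher at 60 weeks in both sorts. Leukocytes are an unlikely source, with a mean of 1.13 CPM over 5 leukocyte genes at 60 weeks and Cd74 at most at 9.01 CPM. In Confetti- cells with fewer than 5 Y-linked reads the median was 0.773, over the limit of 0.329 by more than the SD of 0.0582 over settings. But 56 of 62 cells at 6 weeks and 42 of 47 at 60 weeks were left, so this median could move little. The Y-linked shares there, 9.68% and 10.6%, make the share of male cells an unlikely source in Confetti- cells. That share cannot be told apart as a source in Confetti+ cells. Their median in cells with fewer than 5 Y-linked reads was 0.450, under the limit of 0.564 by less than the SD of 0.322 (mean of the sorts 0.612). A few cells as the source cannot be told apart either: without the 5 cells of each group highest in these genes the mean of the medians was 1.26, but 0.524 with them left out at 60 weeks alone, above the limit of 0.447 by less than the SD of 0.166. Age itself stays open and untested, since each age is 1 pool.

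Some results moved opposite ways in the sorts, which was not tested. Cell cycle genes at 60 weeks had medians of -0.47 in Confetti+ and 1.32 in Confetti- cells, and at 18 weeks of -0.45 and 0.66. At 60 weeks the Confetti+ median was 0.21 in cells with fewer than 5 Y-linked reads and close to 0 over all 378 cells, where the Confetti- median at 18 weeks was 0.25. Innate immune genes at 60 weeks had medians of -0.44 and 0.60, but the Confetti- median was 0.22 in cells with at least 3000 genes, 0.28 over all 378 cells, 0.32 thinned and 0.31 in cells with fewer than 5 Y-linked reads.

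Data outside the comparisons gave a signal too. Y-linked reads marked 50.8%, 76.2% and 60.3% of Confetti+ and 9.68%, 46.6% and 10.6% of Confetti- cells at 6, 18 and 60 weeks. Cells left out made up 25.4% of the Confetti- cells at 60 weeks.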

How the results depend on the processing

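The cells with few Y-linked reads and those without limbal and superficial markers were tests chosen after the data were seen. The count of genes called by edgeR (0 higher in Confetti+, 2 in Confetti-) moved most: DESeq2 called 53 and 1.7e+02, no gene filter 20 in Confetti-, the 25% filter 1 and 16, cells with at least 3000 genes 8 in Confetti-, thinned counts 22 in Confetti-, length-scaled counts 1 and no age block 1 in Confetti-. Leaving out 1 age gave 0 to 4 in Confetti+ and 1 to 31 in Confetti-. Cells with few Y-linked reads gave 0 in Confetti-, thinned 1, and cells without limbal and superficial markers 0. The number of lists past camera was 11 to 15, but 0 with an estimated correlation.

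Some values turned. With the 25% filter the conjunctival list was 0.19 and the cell cycle list -0.10; leaving out 1 age it was -0.0762 to 1.06, Krt14 -0.49 to 0.0716 and Krt5 -0.0118 to 0.17. In cells with few Y-linked reads Chst15 was -0.53 (thinned, -0.15) and the barrier list 0.000424. In cells without limbal and superficial markers Klk10 was 0.69, Krt14 0.0365, Cdkn1a 0.11 and the immediate early list 0.0195. The senescence list (0.0719) was -0.36 with no gene filter and -0.37 without 6 weeks. With age, the conjunctival list was 1.01 at 18 and 1.56 at 60 weeks with the 10% filter, and in cells with few Y-linked reads glycolysis at 60 weeks was 0.0385 and cholesterol at 18 weeks -0.0602. Glycolysis at 60 weeks moved to -0.23 with 10 CPM added and -0.21 with 3000 genes, and immediate early genes at 18 weeks to 0.71 with plain totals and 0.80 in cells with few Y-linked reads. Resolution 0.4 gave 4 clusters and resolution 1.2 gave 10. The cause was not tested.

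The interferon, innate immune, limbal progenitor, cholesterol and basal adhesion lists kept their direction and passed camera at the preset correlation in the other 14 settings, but none passed with an estimated correlation (adjusted p = 0.262 to 0.292). Between the sorts' age ratios r stayed at 0.0911 to 0.126 at 60 and 0.109 to 0.155 at 18 weeks. The sorts were compared within each age, with age as a block. By animal, no paired analysis was possible because the numbers in the labels name cells, not animals. The planned split by Xist was not run. Depth limits shares of genes with few reads: unthinned, Gpha2 was detected in 21.3% of Confetti+ cells at 6 weeks against 9.84% thinned.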

Other observations

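Some measured values belong in no comparison above. The cluster led by stress and signalling genes and the cluster led by Serpinb2 and Muc4 held 56 and 60 of the kept cells. Leukocyte genes were close to absent: Ptprc, the common leukocyte antigen gene, was at most at 0.726 CPM in any group, and Tyrobp and Laptm5 had 0 reads in the 6 sums. Ribosomal protein genes had medians of -0.23 in Confetti+ and -0.13 in Confetti- cells at 18 weeks, with 37 of 48 lower in both sorts, but at percentile 44.6 of random lists in Confetti- cells, whose median was -0.02 with plain totals. Senescence genes at 60 weeks had medians of -0.30 in Confetti+ and 1.03 in Confetti- cells, but -0.84 and 0.72 in cells with fewer than 5 Y-linked reads, where the mean of the medians turned from 0.36 to -0.06. Thinned, the Confetti+ median was -0.10.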
